A study of Nicotiana attenuata with 12 samples.

How the data were processed

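Flowers of the coyote tobacco Nicotiana attenuata were profiled on 1-colour Agilent arrays, 1 array per sample, 12 samples in 4 groups of 3. The groups cross 2 kinds of plant, JAZi VIGS and a VIGS control, with 2 floral stages, 1 and 3. VIGS is virus-induced gene silencing, in which a viral vector carrying a stretch of a gene lowers that gene's transcript. The groups and replicate numbers were taken from the sample titles. The labels conflict on the tissue: titles and source names say flower, while the tissue field and the extraction protocol say leaves. The labels do not say whether replicates came from separate plants, so p-values measure the spread between these samples, which may be technical.

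Per the labels' protocols, Cy3-labelled cRNA was made from 0.5 ug of total RNA after DNase treatment. The intensity values deposited in the scanner files came from Agilent Feature Extraction 10.7.3.1, per the file headers, whereas the submitters' processing notes name version 9.5. The processed signal is a linear intensity after background subtraction, per the file headers, with no scaling between arrays. The median spot signal and the median local background are also linear intensities. The series' value table deposited by the authors holds log2 values whose unit was worked out from the scanner files. Each column had a rank correlation with that array's median spot signal that rounds to 1, and a slope of 0.958 to 1.08 on its log2. Column medians ran from 7.80 to 7.81, so the table has the form of quantile-normalized log2 median signals without background subtraction. This was read from the values, since the labels give no statement of it.

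Each array has 62976 spots, of which 61657 are not controls and represent 57157 probes. A set of 500 probes has 10 spots each and the others have 1. Spots flagged as outliers for non-uniformity or within a probe's population were left out, and 27 probes that lost all their spots on some array were dropped. No spot was flagged as saturated. Log2 of the processed signal minus the array's 75th percentile over non-control spots was averaged over the spots of a probe. Probes were kept where at least 1 group had all 3 arrays flagged well above background. This left 37394 probes for 26959 gene models or other feature IDs and set aside 19763. On 11 arrays 63.1% to 64.9% of probes were well above background, and on the array of control VIGS stage 3 replicate 1 it was 76.1%. The number of arrays limits the precision of each value.

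The files pair probes with feature IDs but with no gene description, and the reference table of 39977 genes matched 0 of these IDs. Gene names, positions and the lists of gene descriptions drawn up beforehand were therefore not used here, and the silenced gene itself was not analysed here. The rule for naming, fixed before the data were examined, falls back on the 2 probes with the largest rise and the 2 with the largest fall among those called, with groups that do not overlap, a condition not set for the interaction. After the values were seen it was narrowed to probes well above background on at least 1 array of each group compared, since values at the floor have no order. That replaced 11 of the 24 picks that size alone gives. For a probe not well above background on any array of a group only a bound was given. The bound sets the bright group's mean against the mean, per array, of the higher of the probe's own value and the lowest value of any probe well above background.

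A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, followed by contrasts, empirical Bayes moderation and Benjamini-Hochberg adjustment over the 37394 probes. Probes were called at an adjusted p below 0.05. The tests are two-sided. Every adjusted p comes from limma, except the Benjamini-Hochberg values given with Fisher's exact test. The fitting code was tested on simulated data with the control means in both lines, the real spread of each probe and 200 changed probes. Noise was drawn independently for each array, so the simulation has no slide structure. For the stage 1 comparison it recovered 76 of 100 probes changed 2-fold and 92 of 100 changed 4-fold. Among the 37394 probes 18 calls were false, a number to be read against the recovered calls.

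The 12 arrays lie on 2 slides of 6, each holding all 4 groups. Slide A holds replicates 1 and 3 of both stage 1 groups and replicate 2 of both stage 3 groups, and slide B the others. The slide was used as a block. Each slide was also fitted alone, which leaves 1 array in some groups, and that array is assumed to vary like the other groups' arrays. Whether replicate numbers pair the samples was checked by correlating deviations from the group means. At stage 1 the pairs gave r = 0.22, 0.58 and 0.39, all over 0.1. At stage 3 the pairs gave 0.06, 0.36 and 0.13, and between stages the values in both lines were below 0. Same-numbered arrays share a slide within a stage and lie on different slides between stages. Arrays of different groups averaged 0.25 on one slide and -0.23 on different slides. Deviations cancel within each group, so a positive mean on one slide brings a negative mean on different slides. The signs of these values therefore cannot tell pairing by number from the slide. On slide A at stage 1, arrays of the same number gave 0.22 and 0.39, and those of different numbers 0.03 and 0.19. On slide B at stage 3, the same number gave 0.06 and 0.13, and different numbers 0.23 and 0.03. These few pairs leave open whether the numbers pair the samples.

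The alternatives chosen beforehand were quantile normalization, median centring, normexp background correction with an offset of 50 on the median signal, no filter, a filter on all 12 arrays, slide block, replicate block, only the 2 groups compared, array weights, a trended robust prior, a 2-fold threshold, the authors' value table, and leaving out each array.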

Results

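The data are 12 arrays of flower RNA, 3 for each of JAZi VIGS and control VIGS plants at floral stages 1 and 3. JAZ proteins are repressors of jasmonate signalling, and the series concerns a member called JAZi and its part in the chemical defence of flowers. The question is how flowers of JAZi VIGS plants differ from control flowers at each stage. Values are log2 signals relative to the array's 75th percentile, given as mean ± SD with n = 3. Probes well above background on all 12 arrays numbered 33922, for 24555 gene models.

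The arrays were ordered first by floral stage. The first principal component held 85.4% of the variance and separated the stages, and the second held 3.89%. Pearson correlations across probes, which are not independent replicates, ran from 0.989 to 0.995 within groups, from 0.987 to 0.994 between lines at one stage, and from 0.899 to 0.917 between stages. Deviations from the group means followed the slide, with a mean correlation of 0.25 over 26 pairs of arrays of different groups on one slide and -0.23 over 28 pairs on different slides. The negative mean follows from the positive one, since deviations cancel within each group.

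**Figure D1:**
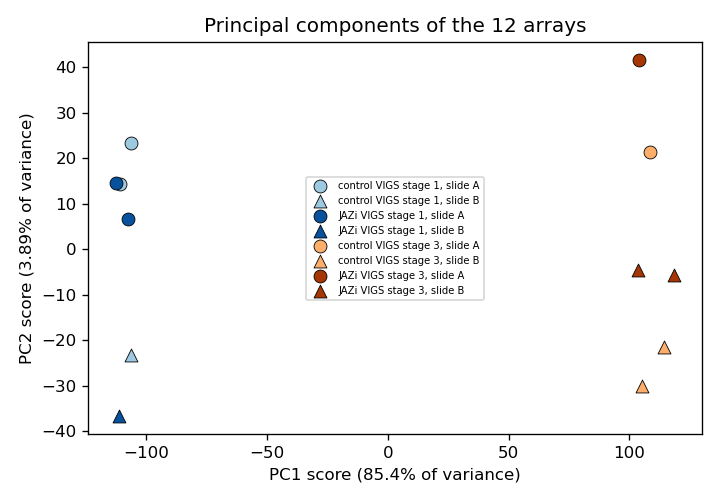
Scores of the 12 arrays on the first and second principal components of the tested probes, coloured by group and shaped by slide. Stage 1 arrays lie at negative and stage 3 arrays at positive scores on the first component, which holds 85.4% of the variance.

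At stage 1, JAZi VIGS flowers had higher signal than control flowers at 270 probes and lower signal at 76, for 231 and 70 gene models. NIATv7_g29371 rose from 3.25 ± 0.04 to 6.99 ± 0.06, a log2 fold change of 3.74 (SE 0.17, adjusted p = 1.65e-05). NIATv7_g32361 rose from 2.34 ± 0.04 to 5.67 ± 0.22, a log2 fold change of 3.33 (SE 0.19, adjusted p = 0.000122). The falls were smaller: NIATv7_g50576 fell by 1.51 on the log2 scale (SE 0.27, adjusted p = 0.0382) and PRID1968057717 fell by 1.47 (SE 0.28, adjusted p = 0.0461), the latter well above background on 2 of 3 JAZi VIGS arrays. Both lost their call under most alternatives and were smaller with normexp, at -0.84 and -0.51, and in the authors' value table, at -0.85 and -0.54. A 2-fold change was reached by 67 of the higher and 12 of the lower probes, and the median log2 fold change was 0.67 among the higher and -0.44 among the lower. Of the called probes 125 had another tested probe in their gene model, and 283 of the 300 other probes differed in the same direction. In 16 of the calls one group was not well above background on any array, and the largest bounds were at least 2.66-fold higher and at least 1.91-fold lower. All 346 called probes had groups that did not overlap. Among all tested probes that share was 24.4%, and 14.2% at stage 3, where chance gives 10%.

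With array weights the stage 1 count was 4120, with 2204 higher and 1916 lower, or 53.5% higher against 78% in the model used here. With the slide as a block it was 708, and with the replicate block, which gives each number 1 effect shared by both stages, 216. Same-numbered arrays lie on different slides at the 2 stages, so that block does not pair the stage 1 arrays by themselves. With only the stage 1 arrays and a replicate block the count was 84. Slide A holds 2 stage 1 arrays against 2, and slide B 1 against 1. Fits of 1 slide have 2 residual degrees of freedom. Their low counts of calls, given further below, therefore do not bear on whether the calls are stable. The log2 fold changes of NIATv7_g29371 were 3.68 on slide A and 3.84 on slide B, and those of NIATv7_g32361 were 3.21 and 3.58; slide A called the first probe. Without JAZi VIGS replicate 1, 2 or 3 the count was 173, 175 or 153, and without control VIGS replicate 1, 2 or 3 it was 104, 199 or 142.

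At stage 3, 21 probes were higher and 33 lower in JAZi VIGS flowers. The same probes led: NIATv7_g29371 rose from 0.20 ± 0.39 to 6.95 ± 0.22, a log2 fold change of 6.75 (SE 0.17, adjusted p = 9.59e-08), and NIATv7_g32361 rose from -0.54 ± 0.31 to 5.66 ± 0.35, a log2 fold change of 6.20 (SE 0.19, adjusted p = 4.11e-07). NIATv7_g38950.t1.cds1 fell by 1.75 (SE 0.24, adjusted p = 0.0408) and NIATv7_g15047.t1.cds1 fell by 1.16 (SE 0.12, adjusted p = 0.00619). NIATv7_g38950.t1.cds1 was well above background on only 1 of 3 JAZi VIGS arrays, lost its call under most alternatives and ran from -2.06 to -0.65 under them. NIATv7_g15047.t1.cds1 lost its call in 6 of 25 alternatives, among them normexp, where it was -0.74, and the authors' value table, where it was -0.79. Of the 33 lower probes 11 were not well above background on any JAZi VIGS array, and the largest bound was at least 3.02-fold lower. The split between higher and lower calls depended on the scaling, the probes kept and the arrays included. Of the calls 38.9% were higher in the model used here. The share was 67.4% with quantile normalization, 58.3% with median centring, 75% with normexp and 72.7% with the authors' value table. With the scaling unchanged it was 52.4% with probes above background on all arrays and 60.7% without control VIGS stage 3 replicate 1. It was lower with no filter, 25.9%, and with the slide block, 30.3%.

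The slide block gave 89 calls at stage 3, the replicate block 23, and a fit of only these groups 3. Slide A holds 1 stage 3 array against 1, and slide B 2 against 2. NIATv7_g29371 had log2 fold changes of 6.25 and 7 on slides A and B, and NIATv7_g32361 5.62 and 6.49. Without control VIGS replicate 1, whose share of probes above background stands apart, the count was 56, with 34 higher and 22 lower. Only 27 of these were among the 54 calls with all arrays, as were 30 of 46 with quantile normalization. With control VIGS replicate 1 left out and the slide as a block, a combination chosen after seeing the data, the count was 879, and these included all 54. Without JAZi VIGS replicate 1 or 3 it was 29 or 27, and without control VIGS replicate 2 it was 19. The stage 1 arrays enter through the shared spread: without JAZi VIGS stage 1 replicate 1, 2 or 3 it was 20, 22 or 14, and without control VIGS stage 1 replicate 1, 2 or 3 it was 18, 18 or 16.

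**Figure D2:**
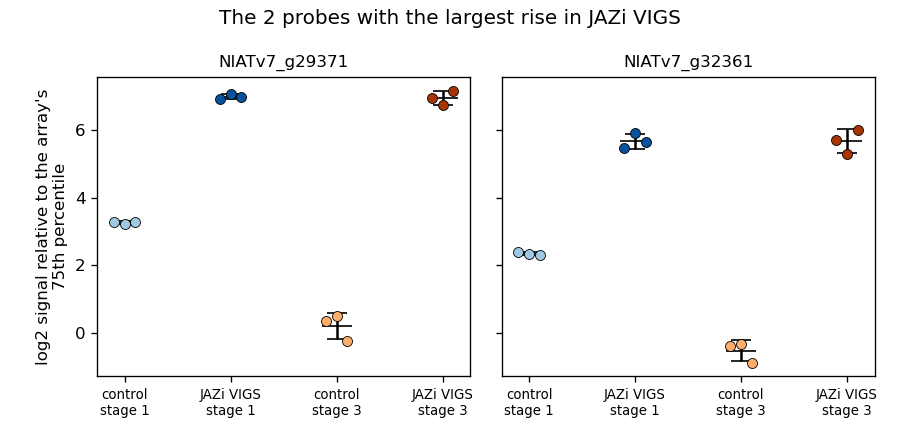
Log2 signal of NIATv7_g29371 and NIATv7_g32361 in each of the 12 arrays by group, with the group mean (bar) and SD (whiskers). JAZi VIGS means are 6.99 and 6.95 at stages 1 and 3 for the first probe and 5.67 and 5.66 for the second.

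Averaged over both stages, 189 probes were higher and 285 lower in JAZi VIGS, for 167 and 260 gene models. NIATv7_g29371 and NIATv7_g32361 had log2 fold changes of 5.24 and 4.77 (SE 0.12 and 0.14, adjusted p = 3.78e-08 and 1.8e-07). PRID1968080795 fell by 0.79 and NIATv7_g45935 fell by 0.77 (SE 0.05 and 0.14, adjusted p = 0.000298 and 0.0333). The changes were small, with 13 of the higher and 6 of the lower probes at 2-fold or more. The share of higher calls was 39.9%, but 73.1% with median centring, 54.9% with normexp, 51.7% with the replicate block, 68.4% with a 2-fold threshold and 55.1% with the authors' value table. Array weights gave 1205 calls, the slide block 974 and the replicate block 201. NIATv7_g45935 lost its call under most alternatives, which gave -0.84 to -0.23. Slides A and B alone gave log2 fold changes of 4.96 and 5.42 for NIATv7_g29371 and 4.41 and 5.03 for NIATv7_g32361. Leaving out a single array gave 155 to 455 calls. The lowest came without control VIGS stage 1 replicate 1, and control VIGS stage 1 replicates 2 and 3 gave 274 and 187. JAZi VIGS stage 1 replicates 1, 2 and 3 gave 171, 212 and 173, JAZi VIGS stage 3 replicates 1 and 3 gave 314 and 196, and control VIGS stage 3 replicate 2 gave 271.

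The fold changes at the 2 stages, which share no array, had a Pearson r of 0.036 and a Spearman rho of 0.051 across 37394 probes, which are not independent replicates. Without NIATv7_g29371 and NIATv7_g32361 the Pearson r was 0.015, so much of the value rests on these probes. On slides A and B alone the Pearson r was 0.037 and -0.039, and without single arrays it ran from -0.027 (without control VIGS stage 3 replicate 1) to 0.123 (without control VIGS stage 3 replicate 3). Called higher at both stages were 8 probes, where independent lists would share 0.152, and called lower at both were 8, against 0.0671. Another 2 were called in opposite directions. Of the stage 1 calls 59% had the same sign at stage 3, and of the stage 3 calls 66.7% had the same sign at stage 1. Both lists use one spread per probe from all 12 arrays, so they are not independent.

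**Figure D3:**
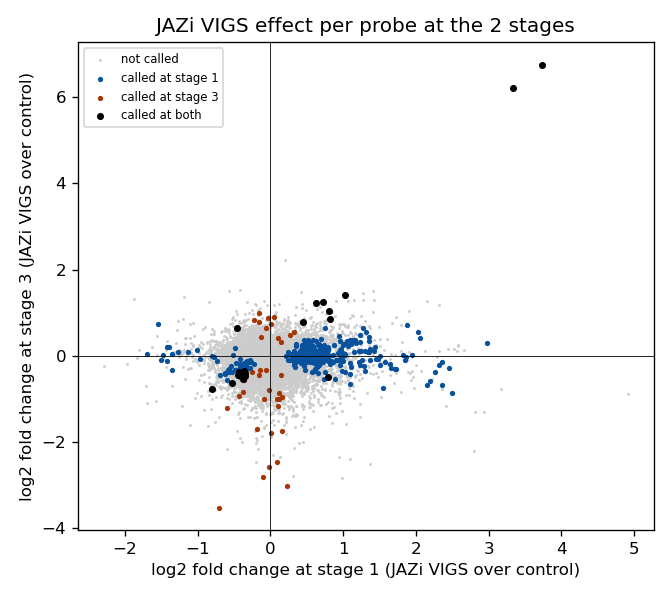
Log2 fold change of JAZi VIGS over control per probe at stage 1 (x axis) and stage 3 (y axis), coloured by the stage at which the probe was called. The pair of probes at the upper right are NIATv7_g29371 and NIATv7_g32361, and the Pearson r over all tested probes is 0.036.

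The effect of JAZi VIGS differed between the stages at 62 probes, more positive at stage 3 for 5 and more negative for 57. NIATv7_g29371 and NIATv7_g32361 had interactions of 3.02 and 2.87 (SE 0.24 and 0.27, adjusted p = 0.00368 and 0.00793). NIATv7_g31306 had an interaction of -2.77 (SE 0.42, adjusted p = 0.0406), a call lost under most alternatives, which gave -3.44 to -1.63, with log2 fold changes of 2.19 at stage 1 and -0.57 at stage 3. NIATv7_g07214.t2.cds1 had -2.73 (SE 0.32, adjusted p = 0.0147), with 2.46 and -0.28. Of the 57 more negative probes 51 were also called higher at stage 1. Both comparisons use the same stage 1 arrays: across probes their r was -0.71, where unchanged groups in 200 simulations gave -0.66, and the covariance was -0.060 against -0.039. Array weights gave 211 calls, the slide block 154 and the replicate block 32. On slide A and slide B the interaction of NIATv7_g29371 was 2.56 and 3.16. The share of higher interactions was 8.06%, against 20% with quantile normalization, 19.4% with median centring and 20.7% with the authors' value table. It ran from 9.76% to 34.6% when a single array was left out. With the slide block and control VIGS stage 3 replicate 1 left out it was 46.5%. Without JAZi VIGS stage 1 replicate 1, 2 or 3 the count was 26, 33 or 27, without control VIGS stage 1 replicate 1, 2 or 3 it was 13, 25 or 18, and without JAZi VIGS stage 3 replicate 3 it was 41.

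Between stage 1 and stage 3 of control flowers, 10875 probes rose and 13508 fell, or 65.2% of those tested. At 2-fold or more were 3987 rises and 3041 falls. The pair of probes for NIATv7_g12333 rose most among probes measured at both stages, NIATv7_g12333.t2.cds1 by 10.66 (SE 0.59, adjusted p = 1.57e-07) and NIATv7_g12333.t1.cds1 by 10.32 (SE 0.50, adjusted p = 6.3e-08). The first of these was well above background on 1 of 3 stage 1 arrays and ran from 8.71 to 11.1 under alternatives. NIATv7_g38604, well above background on 1 of 3 stage 3 arrays, fell by 7.60 (SE 0.51, adjusted p = 6.16e-07) and NIATv7_g26495 fell by 5.98 (SE 0.09, adjusted p = 8.92e-11). The size for NIATv7_g38604 is uncertain: its SD at stage 3 was 1.3, and alternatives gave -8.29 to -5.04, with -8.24 without control VIGS stage 3 replicate 1 and -6.94 without control VIGS stage 3 replicate 3. Another 1038 called probes were not well above background at one of the stages, 722 of them rising, by at least 2076-fold in the largest case, and 316 falling, by at least 16.5-fold. Slide A alone, with 2 stage 1 arrays against 1, gave 22331 calls, slide B alone, with 1 against 2, gave 12981, and the slide block gave a count within 1.5 times. The median over all tested probes was -0.06, and -0.13 with quantile normalization or -0.11 with median centring. With no filter it was 0.25 and the direction of the split turned, with 15431 probes rising and 12878 falling. In JAZi VIGS flowers the split did not turn without the filter, with 9817 rising and 12864 falling. The control stage 3 group holds replicate 1, whose share of probes above background stands apart. Whether that array caused the turn was not tested.

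In JAZi VIGS flowers 10221 probes rose from stage 1 to stage 3 and 13745 fell. NIATv7_g12333.t2.cds1 rose by 10.43 and NIATv7_g12333.t1.cds1 by 9.89 (SE 0.59 and 0.50, adjusted p = 1.77e-07 and 7.97e-08). The first was well above background on only 1 of 3 stage 1 arrays, with an SD of 1.5 there, so its size is uncertain, and it ran from 8.45 to 11.2 under alternatives. NIATv7_g36236 fell by 7.19 (SE 0.42, adjusted p = 2.25e-07) and NIATv7_g38604, well above background on 2 of 3 stage 3 arrays, fell by 6.98 (SE 0.51, adjusted p = 1.11e-06), the latter -7.14 to -5.13 under alternatives. Slides A and B alone gave 20830 and 13479 calls. The stage changes of the lines, which share no array, had a Pearson r of 0.956 across probes, and 21039 probes were called in the same direction in both, or 86.3% of the calls in control flowers. Opposite calls numbered 34. NIATv7_g29371 fell by 3.06 between stages in control flowers (SE 0.17, adjusted p = 1.67e-07), and in JAZi VIGS its stage difference was -0.04 (SE 0.17, adjusted p = 0.843).

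Presence on the arrays was also compared between stages. Well above background on all 6 stage 3 arrays and on no stage 1 array were 487 probes, for 452 gene models, and the converse held for 204 probes, for 197 gene models. Leaving out control VIGS stage 3 replicate 1 changed these to 491 and 367.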

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

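The test of the difference between stages, the slide block and the 100 splits were set beforehand, and all other tests here were chosen after the result was seen. The number of probes whose JAZi VIGS effect differed between stages, 62, was singled out because the difference itself was tested. Of 100 splits of the arrays within stages, the real one included, 3 gave as many calls, and the highest other split gave 98. Most of these splits also regroup the stage 1 arrays, so their share does not exclude chance for the difference between stages. With the stage 1 groups kept, 5 of the 20 splits of the stage 3 arrays gave as many calls as the real 62, with 474 as the highest other. That split exchanges the lines at stage 3 and so equals the comparison over both stages, and the others gave 98, 88 and 72. With the stage 3 groups kept, 2 of 20 splits of the stage 1 arrays gave as many, the real one and that exchange. In each case 20 splits are too few for a share under 0.05. The 4 splits that put 3 slide B arrays in the JAZi VIGS place at stage 3 gave 98, 72, 43 and 7 calls, those that put 3 in the control place gave 32, 29, 19 and 8, and the split with 88 calls mixes the slides. Whether the slide raises the count in these other splits is left open. With the slide as a block the real groups gave 154 calls, all 62 among them. Each slide holds the lines in equal numbers at each stage, so a shift common to a slide's arrays cancels from the interaction by design. The blocked fit is therefore no separate test of such a shift. A slide difference that acts unlike in the lines was not tested. Fits within slides A and B alone leave 1 array in some groups, so their counts do not bear on the 62. NIATv7_g31306, with an interaction of -2.77, and NIATv7_g07214.t2.cds1, with -2.73, were singled out by the same test of the difference.

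NIATv7_g29371 and NIATv7_g32361 also differed between stages, with interactions of 3.02 and 2.87, since both held one level in JAZi VIGS flowers and fell by 3.06 and by 2.88 in control flowers. A fixed-fold rise of the plant's own transcripts would give an interaction near 0, and the smaller interaction was 10.5 standard errors from 0. The interaction also singled these probes out, so this restates the pattern and is no separate test. RNA of the silencing vector carrying a stretch that both probes match stays open: the larger stage difference in JAZi VIGS, 0.0424 in size, is the pattern itself and does not test it. Plant genes that lose their stage control in JAZi VIGS flowers, a biological explanation, also stay open and untested. A ceiling of the scanner is argued against, since the probes lay at different levels, at least 1.15 apart on the log2 scale on each of the 6 JAZi VIGS arrays with SDs up to 0.35, 10 other probes were brighter, and 0 of their spots were marked as saturated.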

How the results depend on the processing

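Fits of each slide alone, of the stage 1 arrays alone, and of the slide block with 1 array less were chosen after seeing the data. Counts of called probes follow in the order stage 1, stage 3, both stages and interaction, against 346, 54, 474 and 62. The slide block gave 708, 89, 974 and 154, the replicate block 216, 23, 201 and 32, no filter 162, 27, 171 and 27, array weights 4120 (53.5% higher), 24, 1205 and 211, and a 2-fold threshold 79, 19, 19 and 36. The slide block without control VIGS stage 3 replicate 1 gave 1447, 879, 1185 and 1648. Slide A alone gave 1, 2, 2 and 0, and slide B alone 0 for each, fits that leave few arrays. Median centring gave 189, 186 and 31 at stage 1, over both stages and for the interaction. At stage 3, normexp gave 12 and only the groups compared 3, and in the authors' values 22 probes were called. The trended robust prior gave 140 interactions. The stage 1 arrays alone with the replicate block gave 84. Leaving out each array gave 104 to 340 at stage 1, 14 to 56 at stage 3, 155 to 455 over both and 13 to 76 interactions. A 2-fold threshold asks more of each probe by construction, and otherwise the cause was not tested.

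The stage counts, 24383 in control and 23966 in JAZi VIGS flowers, moved over 1.5 times only with the 2-fold threshold, to 7028 and 7108, and on slide B alone, to 12981 and 13479. Leaving out an array gave 22205 to 24563 and 21807 to 24687. The replicate block moved neither. The correlation of the JAZi VIGS effects, 0.036, was -0.041 with no filter, 0.099 with probes above background on all arrays, -0.039 on slide B, -0.053 with slide block and 1 array less, and -0.027 to 0.123 without each array. No named probe reversed. Of 612 values of named probes under alternatives 505 stayed called and the others did not. NIATv7_g50576, PRID1968057717, NIATv7_g38950.t1.cds1, NIATv7_g45935 and NIATv7_g31306 lost their call under most alternatives. Where a group was not well above background on any array, signal over background limits the fold change to a bound. The camera tests of gene lists and the values of JAZ repressors, with their alternatives, were not run.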

Other observations

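The calls, the replicate block, the splits drawn for each comparison and the test on negative-control spots well above background were set beforehand. All other tests in this part were chosen after the result was seen. Different probes of one gene model did not always change together between stages. Among 6627 gene models with 2 or more tested probes, 163 in control flowers and 134 in JAZi VIGS flowers had probes called in opposite directions. In 91 the same probes did so in both lines, and in 11 of these both changes were at least 2-fold in control flowers. By class of ID, probes named XLOC were called between stages less often than the others in control flowers, 51.2% against 65.6% (Fisher's exact test, odds ratio 0.551, Benjamini-Hochberg p = 1.42e-18 over 16 tests). The same held for probes named NIATv1, with 50.6% against 65.4% (Fisher's exact test, odds ratio 0.541, Benjamini-Hochberg p = 3.13e-12), while probes named PRID were called more often, 69.7% against 64.9% (Fisher's exact test, odds ratio 1.25, Benjamini-Hochberg p = 2.37e-06). At stage 1 probes named NIATv1 were called more often between lines, 2.09% against 0.907% (Fisher's exact test, odds ratio 2.33, Benjamini-Hochberg p = 0.0221). That result rests on 12 called probes. Probes are not independent, so these p-values are too small. The classes also differ in the probes that passed the filter: 980 of 2283 for XLOC, 575 of 3656 for NIATv1, 2485 of 2810 for PRID and 33354 of 48408 for NIATv7. Whether signal level accounts for the different shares of calls was not tested.

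The array of control VIGS stage 3 replicate 1 stood apart at dim probes: of 16490 probes not well above background on the other 11 arrays, 91.1% were brighter there than on each of the others, where no other array exceeded 1.48% and chance gives 8.33%. A background estimate specific to that array is argued against as the whole cause, since 0.974% of 308 negative-control spots were well above background there and up to 1.3% elsewhere, while 30.6% of these dim probes were. Negative-control spots were raised too, however, with a median of 63 against 52 to 54.8 and 57.1% of them brightest there, so a rise on all spots may account for part of the 91.1%. With the negative-control median of each array subtracted the share was 71.6%, against up to 4.11% on another array. That lies between the bounds of 50% and 80% set for more kinds of transcript in that sample and for a low signal spread over nearly all plant probes, as carried-over genomic DNA could give despite the DNase treatment the labels state, so these cannot be told apart.

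Deviations from the group means followed the slide, and with the slide as a block its coefficient passed for 4758 probes. What else was handled together with each slide is not stated in the labels.

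A hypothesis was that JAZi VIGS shifts the developmental progress of the flowers. The covariance of the stage 1 effect with the stage change in control flowers was 0.0139, against a mean of 0.019 in 200 simulations of unchanged groups with the same shared control arrays, a difference of -0.00511. At stage 3 it was -0.0294 against -0.0179, a difference of -0.0116, and both lay within the simulated 95% range. As a share of the stage change, the shift may lie anywhere from -5.86% to 4% at stage 1 and from -5.81% to 4.82% at stage 3. With 3 arrays per group, a small shift cannot be told apart from none.

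Other splits of the arrays were fitted in the same way. For both stages together 1 of 100 splits, the real one, gave as many as 474 calls and the highest other gave 88. That share is under 0.05 for regroupings of these arrays. Deviations followed the slide and replicates may be technical, so it does not exclude chance differences between the plants sampled. Of the 100 splits 34 part all 3 same-numbered stage 1 pairs, and their highest other was also 88. Regrouping the arrays of 1 stage only gave at most 98 calls at stage 3 and 62 at stage 1, the latter from exchanging the lines, and the replicate block gave 201 with the real groups. For the comparisons of 3 arrays with 3, 10 splits are too few for a share under 0.05. The real value was 346 and the highest other 1 at stage 1, and 54 and 4 at stage 3. Between stages the real values were 24383 in control and 23966 in JAZi VIGS flowers and the highest other 0 in each. Whether replicate numbers pair the stage 1 arrays stays open, since few pairs on slide A compare equal and different numbers on one slide. If they do, 4 of the stage 1 splits part all 3 pairs, and the highest other of these gave 1. The other splits part 1 pair.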
